A study of Homo sapiens with 12 samples.

How the data were processed

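The series holds 12 samples of TIG-1, an established line of normal human fetal lung fibroblasts. 8 are RNA-seq libraries of total RNA from subnuclear fractions, in 4 groups of 2 numbered replicates (NS, CDNS, CDNI, and CDNI from cells given DRB). The other 4 are DNA samples of an experiment named SAR-seq, with and without RNase, and were not analysed here. Per the labels' protocols, nuclei were isolated, nucleoplasmic RNA was released with urea and NP-40 (NS), and the pellet was extracted with ammonium sulfate and taken into a buffer for DNase digestion. The text used here ends at that step, so how CDNS and CDNI were parted is not given in the sources used here. DRB was given for 4 hours at 50 µg/ml, per the labels.

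The submitters' processing notes name TopHat2, Bowtie2, RSEM, deepTools and DESeq2 and the build hg19, with no versions, roles or order. Per the file headers, the first deposited table holds whole-number counts and TPM values for 57773 Ensembl genes in each of the 8 libraries. Whether the deposited counts are estimates of RSEM rounded to whole numbers, and whether counting used strand, is not given in the sources used here. The same table holds adjusted p-values and log2 fold changes that the authors computed for 3 comparisons, with infinite values where a group has no counts. These were used only where the authors' deposited table is named. Per the file headers, a second table from the authors holds TPM values for NS, CDNI and DRB-treated CDNI over 58982 entries, 1209 of them assembled transcripts with no Ensembl ID, and gives a transcript length and a gene type. The type is that of 1 transcript of a gene and can differ from the gene's main type. The deposited TPM values of the Ensembl genes in both tables are the same numbers. 2 further columns of per-sample values in the second table carry a name that no sample's label has, and were not used. For all 57773 Ensembl genes their values equal the deposited TPM of the CDNS libraries in the first table, so they are probably CDNS. Gene symbols came from the same second table, which gave a name other than the ID for 33586 genes.

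Counts were tested in edgeR 4.0.16 under R 4.3.3, as planned before the data were examined. All 8 libraries entered a single quasi-likelihood fit (robust, group as the only term), with 4 residual degrees of freedom, TMM scaling and the filterByExpr filter, which left 21010 genes. The threshold was a Benjamini-Hochberg adjusted p under 0.05 together with an absolute log2 fold change of at least 1. The comparisons were CDNI against NS, CDNS against NS, CDNI against CDNS, and DRB-treated against untreated CDNI. All adjusted p-values of single genes come from edgeR with that adjustment unless another tool is named. The standard error of a log2 fold change is its size divided by the square root of its F statistic. CPM values in the text are scaled by library totals times TMM factors.

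18 gene lists were part of the same plan: nuclear-retained lncRNA, small nuclear and nucleolar RNA, RNA polymerase III transcripts, cytosolic ribosomal protein mRNA, mitochondrially encoded RNA, nuclear-encoded oxidative phosphorylation mRNA, replication-dependent histone mRNA, immediate early genes, fibroblast and extracellular matrix genes, very long genes including common fragile site genes, p53 target genes, proliferation genes, nuclear matrix with hnRNP and SR protein genes, zinc finger genes, transcription elongation and 7SK complex genes, heat shock and stress genes, endoplasmic reticulum and secreted protein mRNA, and markers of other cell types. Each was tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 18 lists, and again with a correlation estimated from the data. With the estimated correlation 0 lists passed in any comparison. Those estimates rest on 4 residual degrees of freedom in a fit without the replicate number, and reached 0.916 for proliferation genes. The plan also held fry, a self-contained test. It asks whether members change at all, not whether they change more than other genes, and its results are not given here. Member counts were made over all genes and adjusted over the list alone.

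Genes named in the text followed a rule from the same plan. It took the 8 genes with the largest positive and the 8 with the largest negative change among those past the threshold with a mean of at least 10 CPM, non-overlapping groups and a symbol. It added the 3 most abundant members of each list and a fixed set of 10 genes, from MALAT1 to GAPDH. RMRP, RPPH1 and BCYRN1, the members of a list with 6 tested genes that the rule leaves out, were named after their values were seen, as were the markers CD79A, APOA1, HBA1, CD3E, SCGB1A1 and CDH5, the silent genes BMP5 and NEUROD6, and the neighbours of named genes in the closing section. Where a group had 0 counts, the fold is a bound against a floor of 3 counts over the group. With 1 to 3 counts the ratio is given with its exact 95% counting interval.

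TPM values, as the authors deposited them, were tested with limma (trend and robust) on log2(TPM + 1) for entries with a mean TPM of at least 1, assembled and annotated ones apart. Shares of counts are percentages of a library's total count. Correlations between comparisons that share libraries were set beside 20 simulated data sets with no change. Lengths were taken from the second table, as no annotation of the authors' build was used here.

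The edgeR test was tested on simulated counts with the means, dispersions and totals of these libraries. For CDNI against NS it recovered 65.7% of 4-fold and 100% of 8-fold changes and called 6 of 20214 unchanged genes. For CDNS against NS it recovered 83.6% and 92.4% and called 23 of 20265, and for DRB-treated against untreated CDNI 65.7% and 87.9%, calling 8 of 20180. Changes of 2-fold were recovered in 4.48%, 11.9% and 5.97% of cases, so a gene that did not pass may still differ by 2-fold. Only 66 or 67 genes changed per fold in each simulation, equally up and down. In the data 65.9%, 66.2% and 30.5% of tested genes passed in these comparisons. The recovery and the false calls therefore need not carry over to them, and the simulation did not challenge the scaling. NS libraries held about 3 to 6 times the counts of the others, and low genes are measured more closely there.

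The alternatives fixed beforehand were the size factors of DESeq2, scaling by library total alone, no filter and a filter at a mean of 10 CPM, the Wald test of DESeq2 1.42.0, a fit of only the 4 libraries compared, the replicate number as a block, the adjusted p alone, each library left out in turn, and other pseudocounts and filters for TPM. Chosen after seeing the data were thinning every library to the smallest total, leaving out pseudogenes, the tests by gene type, and other expression limits for neighbouring genes. Genes that neighbour each other were taken from RefSeq on the GRCh38 assembly by name only. XIST, TSIX and genes of the Y chromosome were left out of the named genes and lists.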

Results

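The study's title places its question in nuclear architecture: what RNA made on chromatin contributes to the structure of chromosome territories. To this end RNA was sequenced from subnuclear fractions of TIG-1, an established line of normal human fetal lung fibroblasts. The nuclear soluble fraction (NS) is the RNA that a buffer of urea and NP-40 released from isolated nuclei. The protocol takes the remaining pellet through ammonium sulfate and towards DNase digestion. The labels do not spell CDNS and CDNI out, and the protocol text used here does not say at which step each was collected. A second deposited table names the same values nucleoplasm for NS and scaffold for CDNI. The fourth group is CDNI from cells treated for 4 hours with 50 µg/ml DRB, an inhibitor of the kinase CDK9 that blocks elongation by RNA polymerase II. Each of the 4 groups held 2 libraries.

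The total counts were 27301150 and 26295948 in the NS libraries, 6964944 and 6466172 in CDNS, 4478988 and 7244072 in CDNI, and 5333697 and 7870386 in DRB-treated CDNI. Of the 57773 genes in the count table, 21010 had enough counts to be tested. Across these genes, which are not independent replicates, log2 CPM (counts scaled by TMM to a common library size) of the 2 replicates correlated with r = 0.982 in NS, 0.973 in CDNS, 0.969 in CDNI and 0.944 in DRB-treated CDNI. Chi-square per degree of freedom between replicates ran from 16.6 in CDNS to 99.8 in NS, so no replicate pair lay within sampling noise. The labels do not say whether replicates came from separate cultures, and every p-value below therefore measures only the spread between these samples, which may be technical.

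Nuclear-retained long noncoding RNAs (lncRNAs), a list of 21 genes with MALAT1 and NEAT1 among them, took 0.874% ± 0.606 of the counts in NS (SD, n = 2). In CDNS their share was 8.45% ± 3.28, in CDNI 10.5% ± 2.60 and in DRB-treated CDNI 5.45% ± 1.67. Most of that share came from the most abundant transcripts: without the 10 most abundant genes of the table the shares were 0.107% in NS, 1.01% in CDNS, 1.09% in CDNI and 1.27% in DRB-treated CDNI, so the lower share with DRB turned to a higher one. Messages of cytosolic ribosomal proteins, which are mature and mostly cytoplasmic, held 2.61% ± 0.348 of NS counts, 0.597% ± 0.0935 of CDNS counts and 0.532% ± 0.0308 of CDNI counts. Transcripts of RNA polymerase III held 2.19% ± 0.618 of NS counts, 0.234% ± 0.0315 of CDNI counts and 1.21% ± 0.267 of counts in DRB-treated CDNI. Mitochondrially encoded RNA, a measure of cytoplasmic carry-over, held 0.176% ± 0.0489 of NS counts, 0.0993% ± 0.0413 of CDNI counts and 0.212% ± 0.130 after DRB. An exact two-sided permutation test of 2 libraries against 2 cannot give a p below 0.333, so these shares are described and not tested.

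**Figure D1:**
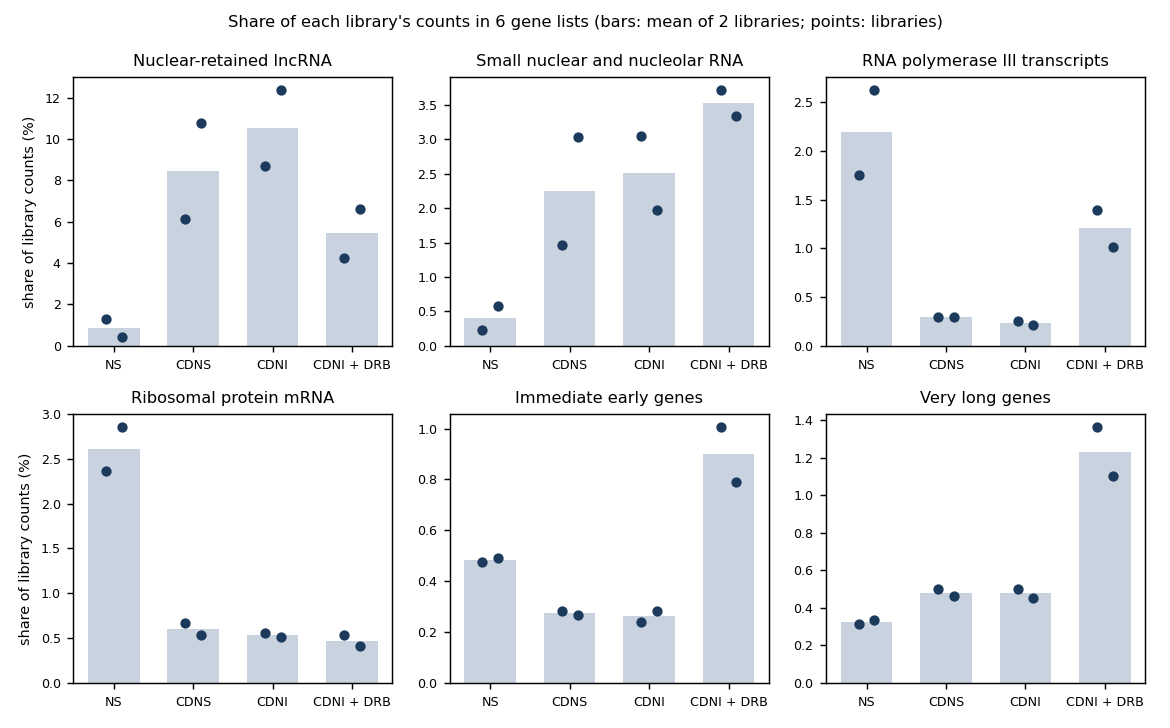
Share of each library's total count (vertical axes, percent, each starting at 0) in 6 gene lists, for the 4 groups on the horizontal axes. Bars are means of 2 libraries and points are the libraries. Nuclear-retained lncRNAs rise from a mean of 0.874% in NS to 10.5% in CDNI, ribosomal protein messages drop from 2.61% to 0.532%, and immediate early genes go from 0.262% in CDNI to 0.898% with DRB.

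CDNI against NS asks which RNAs were more abundant in CDNI than in the nuclear soluble fraction. NEAT1, the scaffold RNA of paraspeckles, was higher by 4.33 on the log2 scale (SE 0.716, adjusted p = 0.000353, n = 2 per group), and KCNQ1OT1, the antisense RNA of an imprinted domain, by 4.21 (SE 0.537, adjusted p = 7.41e-05). ACTB, cytoskeletal actin, was lower by a log2 change of -4.20 (SE 0.560, adjusted p = 9.78e-05) and GAPDH, a glycolytic enzyme, by -4.48 (SE 0.485, adjusted p = 3.08e-05). In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 13847 of 21010 genes passed, 8102 of them higher and 5745 lower in CDNI.

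The split between higher and lower depends on the scaling. With TMM scaling 58.5% of the calls were higher and the median log2 change of all tested genes was 0.22. Scaled by library total alone, 79.5% were higher, 2674 genes were lower and the median was 1.21. Values below use TMM.

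Of the 20 tested nuclear-retained lncRNAs, 16 were higher, 1 was lower and 3 did not pass in CDNI against NS, the same counts as when adjusted over the list alone. Their median log2 change was 2.41 (camera adjusted p = 0.00152, and adjusted p = 0.441 with an estimated correlation). MALAT1, a lncRNA of nuclear speckles, stood at 64727 ± 25298 CPM in CDNI and 11569 ± 7954 CPM in NS (SD, n = 2), a log2 change of 2.48 (SE 0.822, adjusted p = 0.0191). Its call ended without NS replicate 2 (1.88, adjusted p = 0.107) or CDNI replicate 2 (1.97, adjusted p = 0.0802), and that of the imprinted lncRNA MEG3 (2.34, adjusted p = 0.0123) ended without the same libraries, at 1.77 and 1.49. Small nuclear and nucleolar RNAs went both ways, with 24 of 84 higher, 19 lower and 41 not past the test. Adjusted over the list alone the counts were 23 and 19, and the list median was 0.20 (camera adjusted p = 0.680), or 1.12 without NS replicate 2. SNORD3A, the U3 snoRNA of ribosomal RNA processing, was higher by 2.36 (SE 0.686, adjusted p = 0.00993), a call that ended without NS replicate 1 (1.84, adjusted p = 0.0713).

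By the gene type in the second table, 1721 of 2179 tested lincRNAs were higher in CDNI and 38 lower, with a median log2 change of 3.84. Sense-intronic transcripts, which lie inside introns of other genes, gave 353 higher and 2 lower of 387, with a median of 4.46. Antisense genes gave 1221 higher and 30 lower of 1575, and processed pseudogenes 604 higher and 54 lower of 958. Protein-coding genes went mostly the other way, with 2444 higher and 4754 lower of 11816 and a median of -0.66. Genes typed as nonsense-mediated decay (775 tested), retained intron (726) or processed transcript (1722) had medians of 0.10, 0.32 and 0.26. As the type is that of 1 transcript, these may include protein-coding genes, and the split holds for genes typed protein-coding only. The camera adjusted p was 1.51e-21 for lincRNAs and 1.66e-22 for protein-coding genes, and the adjusted p with an estimated correlation was 0.171 and 0.0989. The gene types were tested after the data had been seen. For the lists below, camera took all tested genes as background, noncoding ones included. Medians near -0.66, as for nuclear matrix (-0.96), elongation (-0.98) and p53 genes (-1.16), may thus partly restate the split between protein-coding and noncoding genes. Conversely, the very long (0.22) and zinc finger (0.26) lists lay above the protein-coding median. They were not tested against protein-coding genes alone, so their camera result does not show that they match those genes. In CDNS against NS protein-coding genes stood at -0.65, and the same limits hold there. No source used here says whether counting used strand, so reads of an antisense or intronic gene cannot be told from reads of its host.

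Among cytosolic ribosomal proteins 82 of 86 were lower, 2 higher and 2 not past the test, also adjusted over the list alone, with a median log2 change of -3.43 (camera adjusted p = 2.87e-24, and adjusted p = 0.390 with an estimated correlation). RPL4 was at -3.60 (SE 0.309), RPL3 at -3.14 (SE 0.348) and RPL7A at -3.91 (SE 0.328), with adjusted p of 1.39e-05, 3.51e-05 and 1.30e-05. Nuclear-encoded oxidative phosphorylation genes gave 65 lower, 5 higher and 11 not past of 81, also adjusted over the list alone, with a median of -2.88 (camera adjusted p = 2.56e-15, and adjusted p = 0.293 with an estimated correlation). ATP5B, a subunit of the mitochondrial ATP synthase, was at -3.80 (SE 0.307, adjusted p = 1.23e-05), whereas NDUFS1 of complex I was at -0.39 and did not pass. Of 14 mitochondrially encoded RNAs 10 were lower and 4 did not pass, also adjusted over the list alone, with a median of -1.74 (camera adjusted p = 0.00150, and adjusted p = 0.492 with an estimated correlation). MT-CO1, a subunit of cytochrome c oxidase, was at -2.14 (SE 0.376, adjusted p = 0.000513).

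In CDNI against NS replication-dependent histone messages, which lack poly(A) tails, gave 63 lower and 3 not past of 66, also adjusted over the list alone, with a median of -3.87 (camera adjusted p = 1.78e-11, and adjusted p = 0.459 with an estimated correlation). Genes of the endoplasmic reticulum and secreted proteins gave 25 lower and 1 not past of 26, also adjusted over the list alone, with a median of -2.80 (camera adjusted p = 1.49e-09, and adjusted p = 0.390 with an estimated correlation). The calcium-binding chaperone CALR was at -3.87 (SE 0.457, adjusted p = 4.90e-05). Heat shock and stress genes gave 18 lower and 2 not past of 20, and 19 lower adjusted over the list alone, with a median of -3.26 (camera adjusted p = 4.66e-08, and adjusted p = 0.390 with an estimated correlation). HSPA8, a constitutive chaperone, was at -3.91 (SE 0.475, adjusted p = 5.65e-05). Fibroblast and extracellular matrix genes gave 31 lower and 3 not past of 34, and 32 lower adjusted over the list alone, with a median of -2.41 (camera adjusted p = 1.10e-08, and adjusted p = 0.459 with an estimated correlation). The collagen COL1A1 was at -1.86 (SE 0.612, adjusted p = 0.0186) and fibronectin, FN1, at -1.86 (SE 0.655, adjusted p = 0.0256). The COL1A1 call ended without NS replicate 2 (-1.497) or CDNI replicate 1 (-1.42), the FN1 call without the same libraries (-1.71 and -1.48), and both ended under the library total, at -0.89 each, and with a mean CPM of at least 10, at -1.40 for COL1A1 and -1.39 for FN1. FN1's call also ended when libraries were thinned to the smallest total (-1.47, adjusted p = 0.0550).

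Transcripts of RNA polymerase III divided: 5 of 6 tested were lower and 1 higher, also adjusted over the list alone, with a median of -3.39 (camera adjusted p = 0.00643, and adjusted p = 0.390 with an estimated correlation). RN7SL1, the RNA of the signal recognition particle, was at -6.74 (SE 0.525, adjusted p = 1.20e-05), and RN7SK, which holds the elongation factor P-TEFb inactive, at -3.34 (SE 0.457, adjusted p = 0.000113). The RNAs of RNase MRP (RMRP, -3.11) and RNase P (RPPH1, -3.45) were lower too, and BCYRN1 was the exception, higher by 2.16 (SE 0.276, adjusted p = 7.41e-05).

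Immediate early genes in CDNI against NS gave 19 lower, 1 higher and 12 not past of 32, and 18 lower and 1 higher adjusted over the list alone, with a median of -1.61 (camera adjusted p = 2.55e-05, and adjusted p = 0.390 with an estimated correlation). MYC was at -2.57 (SE 0.385, adjusted p = 0.000196) and CTGF at -2.75 (SE 0.458, adjusted p = 0.000369). The member that was higher, FOS at 2.01 (SE 0.747, adjusted p = 0.0319), stood at 10.2 ± 10.2 CPM in CDNI. Its call ended without NS replicate 1 (1.62), NS replicate 2 (2.48, adjusted p = 0.112) or CDNI replicate 2 (0.18). It also ended without the filter on low counts (adjusted p = 0.233), with only the 4 libraries compared (adjusted p = 0.0652), after thinning (adjusted p = 0.0795) and in DESeq2's test (adjusted p = 0.0978). Proliferation genes gave 22 lower and 5 not past of 27, also adjusted over the list alone, with a median of -2.41 (camera adjusted p = 3.11e-05, and adjusted p = 0.495 with an estimated correlation) that was -1.09 without NS replicate 1. TOP2A, a topoisomerase of dividing cells, was at -2.48 (adjusted p = 0.00684) but at -1.13 without NS replicate 1 and -1.97 without CDNI replicate 2, and its call ended in both and under the library total (-1.46, adjusted p = 0.175). Targets of p53 gave 14 lower and 13 not past of 27, also adjusted over the list alone. Their median was -1.16 (camera adjusted p = 3.02e-05, and adjusted p = 0.441 with an estimated correlation), and -0.19 under the library total. CDKN1A, the cell cycle inhibitor p21, was at -3.38 (SE 0.520, adjusted p = 0.000228).

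Genes for nuclear matrix, hnRNP and SR proteins gave 16 lower, 1 higher and 17 not past of 34 in CDNI against NS, also adjusted over the list alone. Their median was -0.96 (camera adjusted p = 0.000147, and adjusted p = 0.459 with an estimated correlation), and it was 0.02 under the library total, so their direction holds only relative to other genes. The same was true of transcription elongation and 7SK complex genes, with 10 lower and 12 not past of 22, also adjusted over the list alone, and a median of -0.98 (camera adjusted p = 6.59e-05, and adjusted p = 0.390 with an estimated correlation) that became 0.02 under the library total. POLR2A, the largest subunit of RNA polymerase II, was at -1.71 (SE 0.291, adjusted p = 0.000423), and at -0.72 under the library total, where its call ended. Very long genes gave 12 higher, 9 lower and 28 not past of 49, with 11 and 9 adjusted over the list alone. Their median was 0.22 (camera adjusted p = 0.680), and 1.21 under the library total. Zinc finger genes gave 118 higher, 57 lower and 279 not past of 454, with 117 and 55 adjusted over the list alone and a median of 0.26 (camera adjusted p = 0.680). The zinc finger list passed only under the library total, at a median of 1.26 (adjusted p = 0.0321). The very long and zinc finger medians both lay above the -0.66 of protein-coding genes, against which alone they were not tested. Markers of other cell types gave 5 higher, 1 lower and 6 not past of 12, also adjusted over the list alone, with a median of 1.17, or 1.60 with members at 0 counts set to their bound (camera adjusted p = 0.680), and 0.17 without CDNI replicate 1. Among them were the neuronal RBFOX3 (4.35, SE 0.458) and the epithelial CDH1 (4.30, SE 0.376), each below 20 CPM in CDNI.

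**Figure D2:**
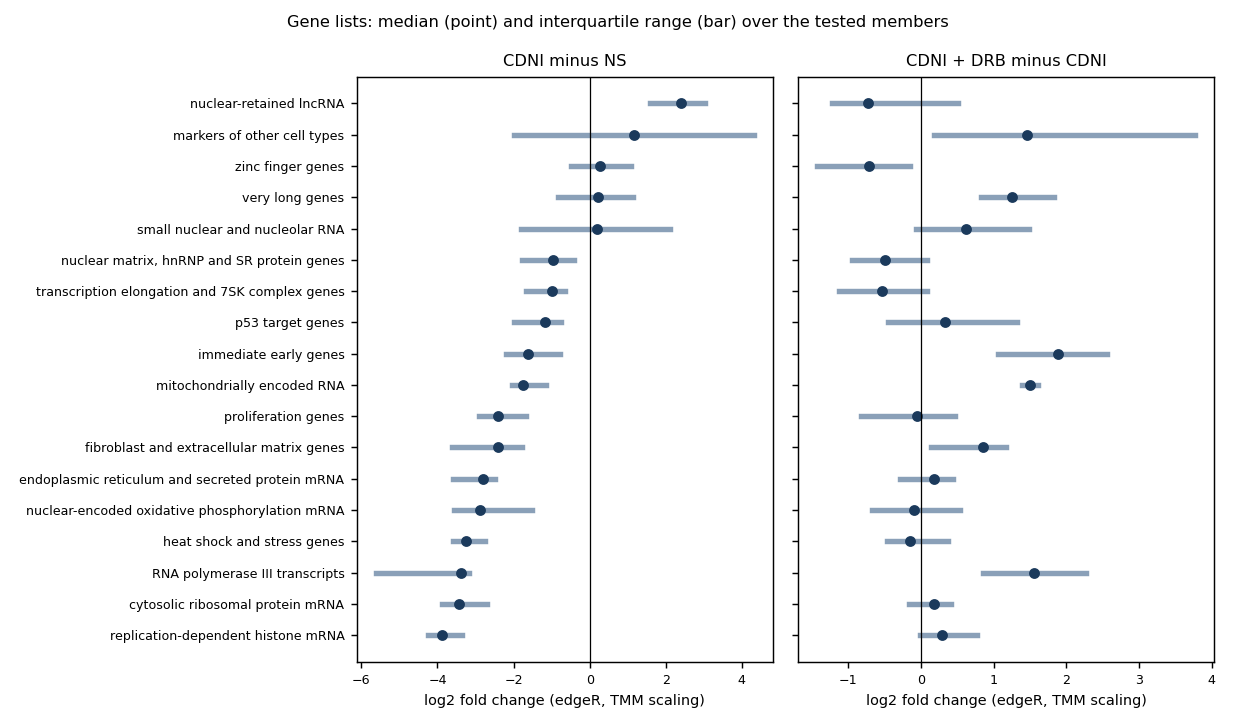
Log2 fold changes (horizontal axes, edgeR with TMM scaling) of the 18 gene lists (vertical axis), for CDNI minus NS on the left and DRB-treated minus untreated CDNI on the right; points are medians over the tested members and bars their interquartile ranges. Histone messages lie lowest on the left at -3.87 and lncRNAs highest at 2.41, and immediate early genes lie highest on the right at 1.89; under the library total the left medians of the nuclear matrix and elongation lists move from -0.96 and -0.98 to 0.02 each, and the right medians of ribosomal protein and endoplasmic reticulum messages from 0.18 and 0.19 to -0.14 each.

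The genes with the largest changes in CDNI against NS included small RNA host loci and intronic transcripts. MIR3648 had 441 counts in CDNI and 1 in NS, a CPM ratio of 1032 with a 95% counting interval of 184 to 40849. MIR663A was higher by 7.69 (SE 0.877), the lncRNA DGCR9 by 7.45 (SE 0.750), the intronic transcripts FOXP1-IT1 and FAM155A-IT1 by 6.15 and 6.13, and KLHL7-AS1 by 6.05. RGR, an opsin of the retinal pigment epithelium, and FCRL5, a receptor of B cells, were higher by 6.45 and 6.40, at 24.8 ± 5.51 and 33.8 ± 0.483 CPM in CDNI (SD, n = 2). At the other end, ISY1-RAB43, LUC7L2 and EIF3CL had 0 counts in CDNI and were at least 208-fold, 164-fold and 144-fold lower, against a floor of 3 counts over the group. The EIF3CL call ended without either NS library, at adjusted p = 0.111 without replicate 1 and adjusted p = 0.0942 without replicate 2, and in DESeq2's test (adjusted p = 0.0578). Without the filter on low counts the calls of EIF3CL (adjusted p = 0.254) and ISY1-RAB43 (adjusted p = 0.0878) ended. These 3 genes, the pseudogenes BZW1P2 and PPIAP22, and RN7SL3 share sequence or position with near-identical genes, so how reads were divided among them is uncertain. Counting intervals and floors cover counting error only.

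CDNS against NS gave nearly the same picture. NEAT1 was higher by 3.89 (SE 0.701, adjusted p = 0.000598) and KCNQ1OT1 by 4.18 (SE 0.536, adjusted p = 7.63e-05), while ACTB was at -4.13 (SE 0.558, adjusted p = 0.000105) and GAPDH at -4.30 (SE 0.481, adjusted p = 3.67e-05), with n = 2 per group. RN7SL1 was at -6.13 (SE 0.510) and RN7SK at -2.81 (SE 0.447). In edgeR's test 13902 genes passed, 8151 higher and 5751 lower. With TMM 58.6% of calls were higher and the median log2 change was 0.24. Under the library total 81.6% were higher, 2418 genes were lower and the median was 1.30. MALAT1 was higher by 2.09 (adjusted p = 0.0377), a call that ended without NS replicate 2 (1.49), CDNS replicate 1 (2.50, adjusted p = 0.0511) or CDNS replicate 2 (1.38).

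In the same 18 lists 14 passed in CDNS against NS, all with adjusted p of 0.301 or more with an estimated correlation. Nuclear-retained lncRNAs gave 16 higher, 1 lower and 3 not past (median 2.10). Ribosomal protein messages gave 81 lower and 3 higher (median -3.35), histones 63 lower (median -3.67), mitochondrially encoded RNAs 11 lower (median -1.93) and p53 targets 17 lower (median -1.36). The lists for small nuclear and nucleolar RNA (17 higher, 15 lower and 52 not past, or 11 higher and 12 lower adjusted over the list alone), very long genes (11 and 7), zinc finger genes (131 and 50) and markers of other cell types (6 and 2) did not pass. The small nuclear and nucleolar median of -0.03 was 1.03 under the library total, and that list passed without NS replicate 1 (0.01, adjusted p = 0.0112) or CDNS replicate 2 (-1.27, adjusted p = 0.00490). The zinc finger list passed under the library total, at a median of 1.35 (adjusted p = 0.0114). The elongation list, at -1.05, stood at 0.02 under the library total. MCL1, a survival gene that responds early, was at -1.02 (adjusted p = 0.0110) with TMM but at 0.04 under the library total, and its call also ended without CDNS replicate 1 (-0.90), with DESeq2 size factors (-0.98), with a mean CPM of at least 10 (-0.53) and after thinning (-0.59). Large single changes were DGCR9 (7.43), MIR663A (6.76) and MS4A6A (6.54, or 10.48 without NS replicate 1) on the higher side. LUC7L2 and BLOC1S5-TXNDC5, with 0 counts in CDNS, were at least 202-fold and 205-fold lower, and the BLOC1S5-TXNDC5 call ended without the filter on low counts (adjusted p = 0.0833).

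The genes called in both comparisons overlapped far more than independent lists would. 7819 genes were higher in both, where 3143 are expected from lists of these sizes, and 5440 were lower in both, where 1573 are expected. A single gene was called in opposite directions. The log2 changes correlated across genes with r = 0.988, against 0.459 for simulated fractions with no change that share the NS libraries, and their covariance was 5.15 against 0.0950. Part of the excess may come from the shared NS libraries.

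CDNI against CDNS asks whether these 2 fractions carry different RNA. No gene was distinguishable with these libraries. MALAT1 was at 64727 ± 25298 CPM in CDNI and 49394 ± 26566 in CDNS (log2 change 0.39, SE 0.779, n = 2 per group), NEAT1 differed by 0.44 (SE 0.625), KCNQ1OT1 by 0.04 (SE 0.470), RN7SK by -0.53 (SE 0.419) and ACTB by -0.07 (SE 0.492). In edgeR's test 0 of 21010 genes passed, with a lowest adjusted p of 0.0794. 122 genes had an unadjusted p under 0.05, and DESeq2 called 3. The 95% interval of the change lay within 2-fold for 47.2% of genes and within 4-fold for 87.9%. Changes of 2-fold were mostly out of reach: on simulated data with these libraries the test recovered 2.99% of 2-fold, 64.2% of 4-fold and 95.5% of 8-fold changes. The authors' deposited table calls 4 genes at an adjusted p under 0.05, C14orf169, BLOC1S5-TXNDC5 and 2 without a symbol, each with no counts in 1 of the 2 fractions.

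No member of any list passed between CDNI and CDNS, and 1 histone gene was lower when adjusted over the list alone. With the preset correlation 6 lists shifted as sets. Small nuclear and nucleolar RNAs were higher in CDNI by a median of 0.24 (camera adjusted p = 3.51e-05). Transcripts of RNA polymerase III (-0.57, adjusted p = 0.0105), proliferation genes (-0.30, adjusted p = 0.00478), histones (-0.28, adjusted p = 0.00478), ribosomal protein messages (-0.11, adjusted p = 0.0317) and oxidative phosphorylation genes (-0.07, adjusted p = 0.0400) were lower. With an estimated correlation each of the 6 had an adjusted p of 0.953. None of the 6 passed without CDNS replicate 1, where the small nuclear and nucleolar median was -0.12 and the histone median 0.46. Other left-out libraries turned or ended them as well: without CDNI replicate 2 the histone and proliferation medians were 0.40 and 0.14 and the small nuclear and nucleolar call ended (0.07). The ribosomal protein call ended without CDNI replicate 1 (-0.02), the oxidative phosphorylation call without any single library of CDNS or CDNI, and the RNA polymerase III call without CDNS replicate 2 or CDNI replicate 2. Without CDNS replicate 2 the small nuclear and nucleolar median was 1.31, and without CDNI replicate 1 the histone and proliferation medians were -1.57 and -1.10. Histone and proliferation shares of counts were higher in replicate 1 of every group. A left-out library therefore also shifts the medians of these 2 lists by replicate number. With the replicate number as a block both lists kept their calls. With DESeq2 size factors the ribosomal protein and oxidative phosphorylation calls ended (adjusted p = 0.0587 each).

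DRB-treated against untreated CDNI asks how the RNA of this fraction changes once elongation is blocked. With DRB 23 of 32 immediate early genes, 27 of 49 very long genes and 3 of 6 RNA polymerase III transcripts were higher, and 152 of 454 zinc finger genes were lower. With an estimated correlation none of these lists passed (adjusted p = 0.0571 for very long genes and adjusted p = 0.495 for each of the others). FOS rose by 4.31 (SE 0.757, adjusted p = 0.00223), from 10.2 ± 10.2 to 207 ± 65.9 CPM (SD, n = 2 per group), though its call ended without the filter on low counts (4.26, adjusted p = 0.0513). RN7SK rose by 3.34 (SE 0.457, adjusted p = 0.000696), from 963 ± 123 to 9740 ± 817 CPM. Here and below, a rise or fall with DRB is relative to the other RNA of the same libraries. The amount of RNA in the fraction was not measured here, so a rise need not be a gain in amount. In edgeR's test 6407 genes passed, 3557 higher and 2850 lower. With TMM 55.5% of the calls were higher and the median change was 0.04, whereas under the library total 39.8% were higher and the median was -0.27. Without CDNI replicate 1 the count was 3913, and without CDNI replicate 2 it was 3658.

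Of 32 immediate early genes 23 rose with DRB, 1 fell and 8 did not pass, also adjusted over the list alone. The median was 1.89 (camera adjusted p = 8.24e-06, and adjusted p = 0.495 with an estimated correlation). MCL1 rose by 2.48 (SE 0.315, adjusted p = 0.000476), MYC by 2.25 (SE 0.382, adjusted p = 0.00188) and CYR61, a secreted matricellular protein, by 2.06 (SE 0.346, adjusted p = 0.00180). CTGF, of the same family, rose by 1.68 (adjusted p = 0.0141), but its call ended without CDNI replicate 1 (1.27) or DRB replicate 2 (1.28). Markers of other cell types moved with the same treatment: 6 of 12 rose, 0 fell and 6 did not pass, with 7 higher adjusted over the list alone and a median of 1.46 (camera adjusted p = 0.0161, and adjusted p = 0.384 with an estimated correlation).

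Of 49 very long genes, several of them at common fragile sites, 27 rose with DRB, 1 fell and 21 did not pass, also adjusted over the list alone. The median was 1.25 (camera adjusted p = 1.39e-08, and adjusted p = 0.0571 with an estimated correlation). LPP, a focal adhesion protein, rose by 2.58 (SE 0.385, adjusted p = 0.00103). EXT1, an enzyme of heparan sulfate synthesis, rose by 1.44 (SE 0.357, adjusted p = 0.0108), a call that ended without CDNI replicate 1 (1.51, adjusted p = 0.0631) or CDNI replicate 2 (1.37, adjusted p = 0.0840). FNDC3B was at 0.95 and did not pass, but passed with DESeq2 size factors (1.04), with a mean CPM of at least 10 (1.02), in DESeq2's test (1.02) and without DRB replicate 1 (1.096). Their share of counts was 0.477% ± 0.0333 in CDNI and 1.23% ± 0.188 with DRB (SD, n = 2).

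Among RNA polymerase III transcripts, made by a polymerase that DRB is not used against, 3 of 6 rose and 3 did not pass, also adjusted over the list alone. The median was 1.56 (camera adjusted p = 0.0118, and adjusted p = 0.495 with an estimated correlation). RN7SL1 rose by 2.29 (SE 0.430, adjusted p = 0.00304) and RN7SL2 by 2.24 (SE 0.464, adjusted p = 0.00469), while RMRP was at 0.74 and RPPH1 at 0.88. Mitochondrially encoded RNA rose in 11 of 14 genes, with 3 not past and 12 higher adjusted over the list alone, and a median of 1.499 (camera adjusted p = 0.00340, and adjusted p = 0.889 with an estimated correlation) that was 0.85 without DRB replicate 1. MT-CO1 rose by 1.38 (SE 0.368, adjusted p = 0.0150), but its call ended without CDNI replicate 2 (1.13), without DRB replicate 1 (0.92) or under the library total (1.09). Small nuclear and nucleolar RNAs gave 13 higher, 2 lower and 69 not past of 84, with 13 and 1 adjusted over the list alone and a median of 0.61 (camera adjusted p = 0.0569). This list passed under the library total (0.34, adjusted p = 0.0157), without CDNI replicate 2 (1.17, adjusted p = 0.0370) and without DRB replicate 2 (0.74, adjusted p = 0.0373).

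Zinc finger genes were the largest list that fell with DRB: 152 of 454 fell, 17 rose and 285 did not pass, with 157 and 18 adjusted over the list alone. The median was -0.72 (camera adjusted p = 2.88e-09, and adjusted p = 0.495 with an estimated correlation). ZNF133 was at -3.91 (SE 0.383, adjusted p = 0.000129), ZNF175 at -3.90 (SE 0.331, adjusted p = 6.72e-05) and ZNF207 at -1.51 (SE 0.287, adjusted p = 0.00317). Genes for nuclear matrix, hnRNP and SR proteins gave 8 lower, 2 higher and 24 not past of 34, also adjusted over the list alone, with a median of -0.50 (camera adjusted p = 0.0325, and adjusted p = 0.898 with an estimated correlation). That call ended without CDNI replicate 2 (-0.36, adjusted p = 0.0513) or DRB replicate 1 (-0.31, adjusted p = 0.165). SRRM2, a protein of nuclear speckles, went against the list and rose by 1.36 (adjusted p = 0.0142), a call that ended without CDNI replicate 1 (1.09). Fibroblast and extracellular matrix genes gave 5 higher and 29 not past of 34, with 3 higher adjusted over the list alone and a median of 0.86 (camera adjusted p = 0.0456, and adjusted p = 0.898 with an estimated correlation). This call ended without CDNI replicate 1 (0.53, adjusted p = 0.697) or DRB replicate 2 (0.12, adjusted p = 0.861), and the median was 1.36 without CDNI replicate 2.

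The other lists did not pass with DRB. Nuclear-retained lncRNAs gave 2 higher, 6 lower and 12 not past of 20, also adjusted over the list alone (median -0.73, camera adjusted p = 0.147). MALAT1 was at -0.80 (SE 0.783, adjusted p = 0.469), NEAT1 at -0.91 (SE 0.629, adjusted p = 0.299) and KCNQ1OT1 at 0.50 (SE 0.472, adjusted p = 0.455). Targets of p53 gave 9 higher and 18 not past of 27, with 9 higher and 1 lower adjusted over the list alone (median 0.32, adjusted p = 0.157), and CDKN1A was at 0.74 (adjusted p = 0.267). The p53 list passed without CDNI replicate 2 (0.74, adjusted p = 0.0418). Transcription elongation and 7SK complex genes gave 2 higher, 8 lower and 12 not past of 22, also adjusted over the list alone (median -0.54, adjusted p = 0.0841). That list passed without CDNI replicate 1 (-0.74, adjusted p = 0.0232) or DRB replicate 2 (-0.83, adjusted p = 0.0186). Ribosomal protein messages gave 7 higher, 3 lower and 76 not past of 86 (median 0.18, and -0.14 under the library total), and oxidative phosphorylation genes 6 higher, 11 lower and 64 not past of 81 (median -0.09). Heat shock genes gave 1 higher, 3 lower and 16 not past of 20 (median -0.15), and genes of the endoplasmic reticulum 2 higher, 1 lower and 23 not past of 26 (median 0.19, and -0.14 under the library total). Of 66 histone and 27 proliferation genes 0 passed in edgeR's test, at camera adjusted p of 0.435 and 0.704. The histone list, with a median of 0.30, passed without CDNI replicate 1 (1.64, adjusted p = 0.00412) or DRB replicate 2 (1.02, adjusted p = 0.0131), and stood at -0.34 without CDNI replicate 2 and -0.72 without DRB replicate 1. ACTB was at 0.79 (SE 0.495), GAPDH at 0.93 (SE 0.424) and COL1A1 at 0.61 (SE 0.595), none of them past the test.

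The largest single gains with DRB were in genes with 0 counts in untreated CDNI. VIT, which encodes the extracellular matrix protein vitrin, went from 0 to 135 ± 2.36 CPM, at least 640-fold higher (floor of 3 counts over the group). CYP26B1, which degrades retinoic acid, was at least 363-fold higher, ADAM30 at least 358-fold (its call ended in DESeq2's test, adjusted p = 0.0609), the neural transcription factor SIM1 at least 305-fold, PHYHIPL at least 279-fold, the neuronal sodium channel SCN1A at least 247-fold and RASSF10 at least 206-fold. Of the 3557 genes that rose, 926 had 3 counts or fewer over the CDNI libraries and 558 had 0. The largest losses were in the imprinted noncoding RNAs MEG9 (-5.52, SE 0.790) and MEG8 (-4.15, SE 0.616) and in MIR181A1HG (-4.54, SE 0.408), the host of a microRNA pair. TAF1D, a factor of RNA polymerase I and a host of small nucleolar RNAs, was 16.0-fold lower (SE 0.489 on the log2 scale, adjusted p = 0.000386). H2AFY, the histone variant macroH2A1, was at -3.90 (SE 0.286, adjusted p = 4.21e-05). By gene type, 137 of 387 sense-intronic transcripts fell and 26 rose (median -1.10, camera adjusted p = 2.53e-09, and adjusted p = 0.886 with an estimated correlation), while 586 of 2179 lincRNAs rose and 121 fell.

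The change with DRB was nearly unrelated to a gene's difference between CDNS and NS. DRB-treated minus untreated CDNI shares no library with CDNS minus NS, and across 21010 genes their log2 changes gave r = -0.0473 and rho = 0.0287, as a description, since genes are not independent replicates. The 8151 genes higher in CDNS than in NS had a median DRB change of 0.11 (interquartile range -0.61 to 0.87), the 5751 lower ones -0.00 (-0.68 to 0.65) and the 7108 others -0.02. With CDNI minus NS, which shares the untreated CDNI libraries, r was -0.0499, against -0.522 in simulated data with no change. The covariance was -0.183 against -0.117.

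The second table adds 1209 transcripts that the authors assembled and that carry no gene annotation, in units of TPM. They held 0.0678% ± 0.0242 of the TPM in NS, 0.761% ± 0.0298 in CDNI and 1.12% ± 0.215 in DRB-treated CDNI (SD, n = 2). Of 904 tested with limma on log2(TPM + 1), 822 were higher and 0 lower in CDNI than in NS, with a median of 2.21. Which libraries they were assembled from was not established here. Transcripts assembled from CDNI reads would be higher there by construction, so the 822 against 0 may be set by how the list was made. With DRB 146 were higher, 34 lower and 724 not past, with a median of 0.07. Without DRB replicate 1 the lower ones were 62 and the median was -0.19, and without CDNI replicate 1 the lower ones were 22 and the median was 0.17, while without DRB replicate 2 the median was 0.28. On this scale, which understates the change of low transcripts, 9801 annotated genes were higher and 2860 lower in CDNI than in NS, and 2553 were higher and 5188 lower with DRB. The split of the DRB calls is thus the opposite of that in edgeR, with a median over annotated genes of -0.42; unit, scaling, test and filter all differ between the 2.

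Transcript length went with the change between CDNI and NS over all tested genes, but not among genes matched on expression. In CDNI against NS the median log2 change was 3.35 in the fifth of genes with the shortest transcripts (median 573 bases) and -0.43 in the fifth with the longest (median 4538 bases). Among genes matched on mean expression the same medians were 0.93 and 0.90. With a mean CPM of at least 10 the difference, longest minus shortest, turned from -3.78 to 0.25. With DRB the medians of the shortest and the longest genes were 0.17 and 0.16, but 0.21 and 0.51 among genes matched on expression, and the difference moved from -0.01 to 0.27 with a mean CPM of at least 10. These lengths are of transcripts, not of genes with introns.

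The authors' deposited table holds their own comparisons. For CDNI against NS it lists 12270 genes at an adjusted p under 0.05, 7146 of them higher and 5124 lower in CDNI, and 11829 of these also passed here, each in the same direction. For DRB the authors' deposited values list 3733 genes, 2124 higher and 1609 lower, of which 3693 also passed here in the same direction.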

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

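With a correlation estimated from the data, 0 lists passed in CDNI against NS, 0 in CDNS against NS, 0 in CDNI against CDNS and 0 with DRB. Scaled by library total only, genes lower numbered 2674 in CDNI against NS and 2418 in CDNS against NS, 1 gene was higher in CDNI than in CDNS, and MCL1 turned to 0.038 in CDNS against NS. The cause was not tested. Without a filter on low counts CDNI against CDNS gave 15 genes, 6 higher and 9 lower, and DESeq2's Wald test gave 3, 2 higher and 1 lower. A filter at a mean CPM of at least 10 tests fewer genes: 6247 passed in CDNI against NS (3274 higher, 2973 lower), 6241 in CDNS against NS (3283 and 2958) and 3131 with DRB (1567 and 1564). Under that filter the correlation of the DRB change with that of CDNS against NS was 0.0402, and the longest-minus-shortest length difference turned to 0.25 in CDNI against NS and 0.19 in CDNS against NS. The cause was not tested. Without the 10 most abundant genes the lncRNA shares were 0.107% in NS, 1.01% in CDNS, 1.09% in CDNI and 1.27% with DRB. Shares in CDNS then were 0.111% for mitochondrial RNA, 0.347% for RNA polymerase III transcripts and 0.293% for small nuclear and nucleolar RNA. In CDNI they were 0.632% for ribosomal protein messages, 0.277% for RNA polymerase III transcripts and 0.259% for small nuclear and nucleolar RNA, the last at 0.466% with DRB. With a TPM pseudocount of 0.1, 1 unannotated transcript was lower in CDNI than in NS.

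Leaving out each library in turn, where a lone library is assumed to vary like the other groups, gave 12812 to 14238 genes in CDNI against NS (7675 to 8597 higher, 5137 to 5710 lower; 14 to 14 lists) and 12753 to 14312 in CDNS against NS (7581 to 8662 and 5172 to 5703; 14 to 15 lists). CDNI against CDNS gave 0 to 2 genes (0 to 1 higher, 0 to 2 lower) and 0 to 9 lists. DRB gave 3658 to 5759 genes (2017 to 3171 higher, 1641 to 2709 lower) and 7 to 10 lists. Unannotated transcripts were higher in 777 to 869 and lower in 1 to 2 cases in CDNI against NS, and higher in 102 to 192 and lower in 22 to 62 with DRB. The direction of camera's test turned for 8 list values that passed before or after, all in CDNI against CDNS. The medians of these lists ran as follows: small nuclear and nucleolar RNA (-0.12 to 1.31; lowest without CDNS replicate 1), histones (-1.57 to 0.46; turned without CDNS replicate 1, and without CDNI replicate 2 at 0.40), immediate early genes (-0.38 to 0.20), matrix genes (-0.57 to 0.52), proliferation (-1.10 to 0.14), heat shock (-0.34 to 0.32) and endoplasmic reticulum genes (-0.38 to 0.34). The cause was not tested. Of values of named genes, 1063 kept their side of the threshold, 63 were weaker and 18 stronger. Of those past the threshold before or after, 0 turned in sign. A turn in a gene that passed in neither fit is counted among the 1063.

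The labels do not say what libraries of the same number share. Their deviations correlated at 0.0969 to 0.321 over the 6 pairs of groups. The histone share was higher in replicate 1 of every group (0.351% and 0.129% in NS, 0.0630% and 0.0156% in CDNI). The proliferation share was too, and the matrix share was higher in replicate 2. The small nuclear and nucleolar share did not keep to a replicate number. Such repeated differences could come from a shared culture or batch, which the labels do not name and the main fit does not model. With the replicate block the counts were 14093, 14101, 1 (1 higher) and 7112 in the order CDNI against NS, CDNS against NS, CDNI against CDNS and DRB. Of 72 list values 69 kept their side under the block. In CDNI against CDNS it kept 4 of the 6 list calls, and ribosomal protein messages (adjusted p = 0.0578) and oxidative phosphorylation genes (adjusted p = 0.0992) did not pass, while with DRB small nuclear and nucleolar RNA passed (0.67, adjusted p = 0.0383). FOS in CDNI against NS (adjusted p = 0.0864) and EIF3CL in CDNI against NS (adjusted p = 0.0982) and CDNS against NS (adjusted p = 0.0917) did not pass under it. Leaving out 1 library also breaks up the numbers by construction. Under the block 276 values of named genes kept their side. The other planned settings kept most named gene values: 283 with DESeq2 size factors, 277 with DESeq2's test, 279 with only the 4 libraries compared and 251 under the library total. Chosen after seeing the data, thinning to the smallest total left 11891, 11858 and 6096 calls (DRB last), and leaving out pseudogenes left 12735 in CDNI against NS and 5641 with DRB.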

Other observations

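Genes that were silent in untreated CDNI and CDNS and rose with DRB lay next to expressed genes more often than other silent genes did. VIT lies between FEZ2 (62.7 CPM in untreated CDNI) and STRN (33.2 CPM), ADAM30 next to NOTCH2 (286 CPM), SIM1 next to ASCC3 (266 CPM) and RASSF10 next to TEAD1 (357 CPM). Among 4172 silent protein-coding genes, with 3 counts or fewer in untreated CDNI and also in CDNS, 187 of 249 that rose (75.1%) had an adjacent gene at 10 CPM or more, against 1871 of 3923 others (47.7%). The odds ratio was 3.31 (95% interval 2.45 to 4.51, Fisher's exact p = 1.37e-17) for adjacent genes. It was 3.01 (2.19 to 4.21) for genes 2 places away, 2.30 (1.69 to 3.17) for 3 places and 1.40 (1.06 to 1.88) for 5 places. The excess was thus not particular to the adjacent gene. Genes side by side share neighbours, and some of the risen genes adjoin each other. They are not independent, so the intervals and the p overstate the certainty. The limits of 10 CPM and 3 counts were set before the test ran but stood in no written prediction, and limits of 1, 5 and 20 CPM, chosen after seeing the data, gave odds ratios of 4.51, 3.22 and 3.38. BMP5 rose with neighbours at 0 and 0.144 CPM and NEUROD6 with neighbours at 0 and 2.45 CPM, so an expressed neighbour is not a condition for every gene.

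3 technical explanations for these gains were weighed, with the DRB group as the only biological contrast in the design. The neighbour result, an odds ratio of 3.31, is what reads running on from an expressed neighbour could give. The interval for genes 2 places away (2.19 to 4.21) spans that value. The result therefore does not part run-on from a wider excess of expressed genes nearby. The order of genes came from RefSeq on GRCh38, strand was not used, and run-on is a hypothesis that read positions would have to test. Evenly spread DNA was set aside, as the top 10% of silent genes held 6.49 and 6.97 times the share of a Poisson draw by length, and 66.5% and 64.9% of silent genes had no read. The silent genes in that draw included those that rose, and DNA left unevenly over the genome was not tested. RNA of another cell type was left open: 6 of 25 fixed markers rose (24%, exact 95% interval 9.36% to 45.1%), among them CD79A (53 and 34 counts against 0) and APOA1 (12 and 33 against 0), while HBA1, CD3E, SCGB1A1 and CDH5 had 0 counts with DRB. The bound set before the test was 25% of the markers, and 24% lies under it by less than 1 gene and the opposite bound of 50% was not met by 6 of the 21 markers with reads (28.6%, 11.3% to 52.2%), but each interval spans its bound, so the explanation was left open after the value was seen.

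The number of genes that differ between CDNI and NS was weighed against library depth. With every library thinned to the smallest total, 81.2% of the calls were left and 100% of these kept their direction, so depth does not account for most of them. No biological explanation was tested beyond the groups compared.

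That no gene differed between CDNI and CDNS was weighed against a repeated library and against depth. The closest pair, CDNS replicate 2 and CDNI replicate 2, differed by a chi-square per degree of freedom of 4.48, above the sampling noise of 1, and the farthest pair by 24.7, so no library stands under both labels. The replicates of CDNI differed by 17.3 and those of CDNS by 16.6, more than the closest pair across the fractions. Depth was left open, since 64.2% of simulated 4-fold changes were recovered, between the limits set before the test. The simulation carried the spread between replicates as well as the depth, so it cannot tell one from the other. No biological explanation was tested.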
